A study of Mus musculus with 22 samples.

How the data were processed

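RNA from mouse blastocysts at embryonic day 3.5 was profiled on 22 Illumina MouseRef-8 BeadChip arrays, per the labels. Per the submitters' protocol notes, 150 ng of total RNA was amplified and biotin-labelled with a 12 h in vitro transcription. The labels name the strain (B6 or CD1) and the culture medium or in vivo growth of each array, and arrays were placed in 8 groups from these labels. Of these, 7 groups had 3 arrays and the CD1 KSOM group had 1.

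The deposited table of raw values gives, for each of 25697 probes and each array, a linear bead intensity that was not normalized between arrays. Beside each intensity, the deposited table gives a detection p-value, the p of the probe against the negative controls of its array, whose method is not stated. The authors also gave a second table of log2 values. In it the sorted values of any 2 arrays differed by at most 0.000774, so the authors had quantile-normalized them, with a median of 3.61 and a range of 1.56 to 15.1. Its order of probes within each array matched that of the intensities, with a Spearman correlation of 1. The labels name BeadStudio 3.2, RMA and lumi as processing tools and state no order of steps or settings.

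Intensities were background-corrected, offset by 16, quantile-normalized and put on the log2 scale with the neqc function of limma 3.58.1 in R 4.3.3, with the detection p-values standing in for the negative-control probes. Probes with a detection p under 0.05 on at least 3 arrays were kept, which left 12992 probes. The annotation deposited with the array gave 1 symbol to 23978 probes, several to 0 and none to 1719. The entrez identifiers of 23962 probes matched the RefSeq gene table, and this match updated 0 symbols. Each gene was represented by its kept probe with the highest mean, giving 9345 tested genes out of 16593 with a symbol. Of the tested genes, 7168 had 1 kept probe and 2177 had more. No genome build was given in the sources used here, so no coordinates are reported.

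A linear model with 8 group means was fitted to all 22 arrays with limma (lmFit and eBayes), with 14 residual and 3.51 prior degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. All limma tests were two-sided. The contrasts set each medium against in vivo growth and against the other media within a strain, CD1 against B6 in vivo, the difference between strains in each medium effect, and HTF and ISM1 jointly against in vivo over both strains. The contrasts, the tests, the gene lists and the rule for naming genes were fixed before the data were examined. A further 4 contrasts averaged an effect over the strains or a strain difference over HTF, ISM1 and in vivo, and were chosen after seeing the data.

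The text names, per contrast, up to 8 raised and 8 lowered genes with the largest log2 difference among those called with all arrays of one group above all of the other, leaving out clone and model names. It also names up to 4 called members of each gene list and, whatever their result, Cdx2, Gata3, Eomes, Pou5f1, Nanog, Sox2, Gata6, Gata4, Sox17, H19, Igf2, Peg3, Mest, Asns, Hspa1b and Trp53. Other named genes were chosen after their values were seen, and the text says so. Where a gene was detected on no array of one group, that group was set to its arrays' detection floor and the fold is given as a lower bound.

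The 23 gene lists covered trophectoderm, epiblast and inner cell mass, primitive endoderm, imprinted genes, fluid transport and cell junctions, glycolysis, oxidative phosphorylation, cholesterol synthesis, the amino acid starvation response, amino acid transporters, endoplasmic reticulum stress, heat shock, p53 targets, oxidative stress, the cell cycle, DNA methylation and chromatin, oocyte transcripts, genome activation at the 2-cell stage, reproductive tract epithelium, blood and immune cells, cumulus cells, sex-linked genes and ribosomal proteins. Each was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast. Camera with an estimated correlation and limma's fry were run beside it. Fry tests whether a list's genes moved on balance one way and does not compare them with other genes. Single members were also adjusted over the list alone.

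The effects of HTF and of ISM1 were correlated between strains across genes, with arrays relabelled within each strain in 400 ways. Correlations between effects that shared in vivo arrays were set against 20 simulations without effects. Distances of cultured arrays to the in vivo mean were tested with a one-sided exact permutation test. The CD1 KSOM array was compared with the CD1 in vivo mean without a test, and its list medians with 10000 random lists of matched expression. The test procedure was tested on simulated data with 9345 genes: for B6 HTF against in vivo it recovered 10 of 100 genes changed by 1 on the log2 scale and 61 of 100 changed by 2. For the HTF effect averaged over the strains it recovered 32 of 100 and 82 of 100, with 8 false calls.

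The alternatives tried were array quality weights, no background correction, an RMA-style background model with an offset of 50 (reimplemented, since its package was not used here), a detection p under 0.01, no filter, median scaling, replicate number as a block, all probes, leaving out each array, fitting only the compared arrays, a trended robust prior, a 1.5-fold minimum and the authors' log2 values. A developmental stage score as a covariate, median intensity as a covariate, leaving out the 3 dimmest arrays, leaving out each array from the tests of the called lists, and leaving out each in vivo array from the CD1 KSOM comparison were added after seeing the data. The stage score was the mean standardized level of the primitive endoderm list minus that of the oocyte list. Deviations from the group means correlated between arrays with the same replicate number at 0.18, 0.177 and 0.213 for CD1 HTF and CD1 ISM1. The numbers were taken to pair these arrays, though the labels do not say what a number marks. Over all 27 pairs with the same number r ranged from -0.718 to 0.453, so this pairing is uncertain. A block for slide was not run, since the slide of each array is not given in the sources used here. No per-sample column was left unused.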

Results

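Gene expression was measured on 22 one-colour arrays hybridized with RNA from mouse blastocysts at embryonic day 3.5. The embryos were of the inbred B6 or the outbred CD1 strain and had developed in vivo or in 1 of 3 embryo culture media, KSOM, HTF and ISM1. The B6 KSOM, B6 HTF, B6 ISM1, B6 in vivo, CD1 HTF, CD1 ISM1 and CD1 in vivo groups had 3 arrays each, which the labels call biological replicates. The CD1 KSOM group had 1. The median intensity of an array ranged from 90.6 on CD1 in vivo replicate 1 to 154 on B6 KSOM replicate 1, and the number of probes detected at p under 0.01 from 7410 to 9400. The CD1 in vivo arrays were the dimmest group, with a mean median intensity of 104 ± 11.3 (SD, n = 3), and correlated least among themselves across genes (mean r = 0.861). The B6 HTF arrays correlated most among themselves (mean r = 0.969). Among the groups of 3 arrays, 15 arrays correlated better with the closest other group of their strain than with their own. Taking the closest of several groups favours such a result even where groups are alike. The number of arrays limits the precision: the median SE of a log2 difference between groups of 3 was 0.43.

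The first comparison asked how blastocysts grown in HTF differed from blastocysts grown in vivo. In B6, limma called 1 of 9345 genes, Cstdc1, a member of the cystatin family of protease inhibitors. Cstdc1 was 4.05-fold higher in HTF (log2 difference 2.02, SE 0.30, adjusted p = 0.0328 by limma), with a mean log2 intensity of 7.79 ± 0.37 (SD, n = 3) in HTF and 5.77 ± 0.34 in vivo. In CD1, limma called 1 gene, Pga5, which encodes a pepsinogen and was 6.44-fold lower in HTF (log2 difference -2.69, SE 0.42, adjusted p = 0.0467 by limma). Cstdc1 was detected on 0 of 3 CD1 in vivo arrays and was at least 1.83-fold higher in CD1 HTF without a call (adjusted p = 0.269 by limma). Pga5 in B6 differed by -0.59 (adjusted p = 0.999 by limma). The difference between strains was not called for either gene (each adjusted p = 1 by limma). Spc24, a kinetochore gene chosen after its values were seen, was next in CD1 with a log2 difference of -1.85 (adjusted p = 0.0592 by limma), but its other probe differed by 0.08. Of all genes, 317 in B6 and 660 in CD1 had an unadjusted p under 0.05, where chance gives 467 if all groups have the same spread. The fit pooled the spread over groups that differed in it (mean r among replicates 0.969 in B6 HTF and 0.861 in CD1 in vivo). A count above or below 467 therefore shows neither an effect nor its absence. All HTF arrays lay above or below all in vivo arrays for 10.8% of genes in B6 and 10.4% in CD1, where chance gives 10%. The call of Cstdc1 in B6 did not hold without B6 HTF replicate 1 or 2 or without B6 in vivo replicate 1 or 2, each of which left 0 genes. The B6 count was 1159 with array quality weights and 0 with the replicate block, with the authors' values and when only the compared arrays were fitted. In CD1, leaving out any 1 HTF array left 0 genes, and leaving out in vivo replicate 1, 2 or 3 gave 3, 5 or 29. The CD1 count was 0 with array quality weights, the RMA-style background, all probes, median scaling, a trended robust prior and only the compared arrays. Median scaling in place of quantile normalization shifted the median of all genes by 0.303 on the log2 scale in the CD1 comparison.

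Averaged over the strains, a contrast chosen after seeing the data, HTF differed from in vivo for 19 genes by limma, of which 11 were higher and 8 lower in HTF. Socs3, which encodes an inhibitor of cytokine signalling through STAT3, was 9.92-fold lower in HTF (log2 difference -3.31, SE 0.63, adjusted p = 0.0364 by limma) and was lower on all HTF arrays than on all in vivo arrays of its strain. Magea2, of the X-linked MAGE family, was 3.91-fold higher (log2 1.97, SE 0.30, adjusted p = 0.00861 by limma). Cstdc1 was at least 2.72-fold higher (adjusted p = 0.00335 by limma). Ero1b, which reoxidizes protein disulfide isomerases in the endoplasmic reticulum, was at least 2.21-fold higher (log2 1.43, SE 0.26, adjusted p = 0.0282 by limma). Ckmt1, a mitochondrial creatine kinase, was 2.41-fold lower (log2 -1.27, SE 0.17, adjusted p = 0.00388 by limma). The other genes raised under the naming rule were Cd28 (at least 4.41-fold), Creld1, Magea5, Uchl1 and Col26a1. The other genes lowered were H2ac18 (at least 3.39-fold), Fxyd4, Echdc3, Neu1 and Pdlim1. The second probes of Cd28 and Magea5 differed by only 0.24 and 0.25 on the log2 scale, while that of Fxyd4 differed by -1.63. Tgfbr2, Sec24d, Dpysl5 and Pga5 completed the 19 and were chosen after their values were seen. Of these 19 genes, Ckmt1, Cstdc1 and Magea2 were called in each of 26 settings. Socs3 was called in 10 of them, Ero1b in 11 and Dpysl5, the fewest, in 6. An unadjusted p under 0.05 was reached by 771 genes. The count fell to 6, 8 or 7 without B6 HTF replicate 1, 2 or 3, to 9, 5 or 12 without B6 in vivo replicate 1, 2 or 3, and to 5, 5 or 9 without CD1 HTF replicate 1, 2 or 3. Without CD1 in vivo replicate 3 it was 56, with array quality weights 165, with the replicate block 7 and with only the compared arrays 10. Under median scaling, which shifted the median of all genes by 0.135, the split was 18 higher and 2 lower.

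**Figure D1:**
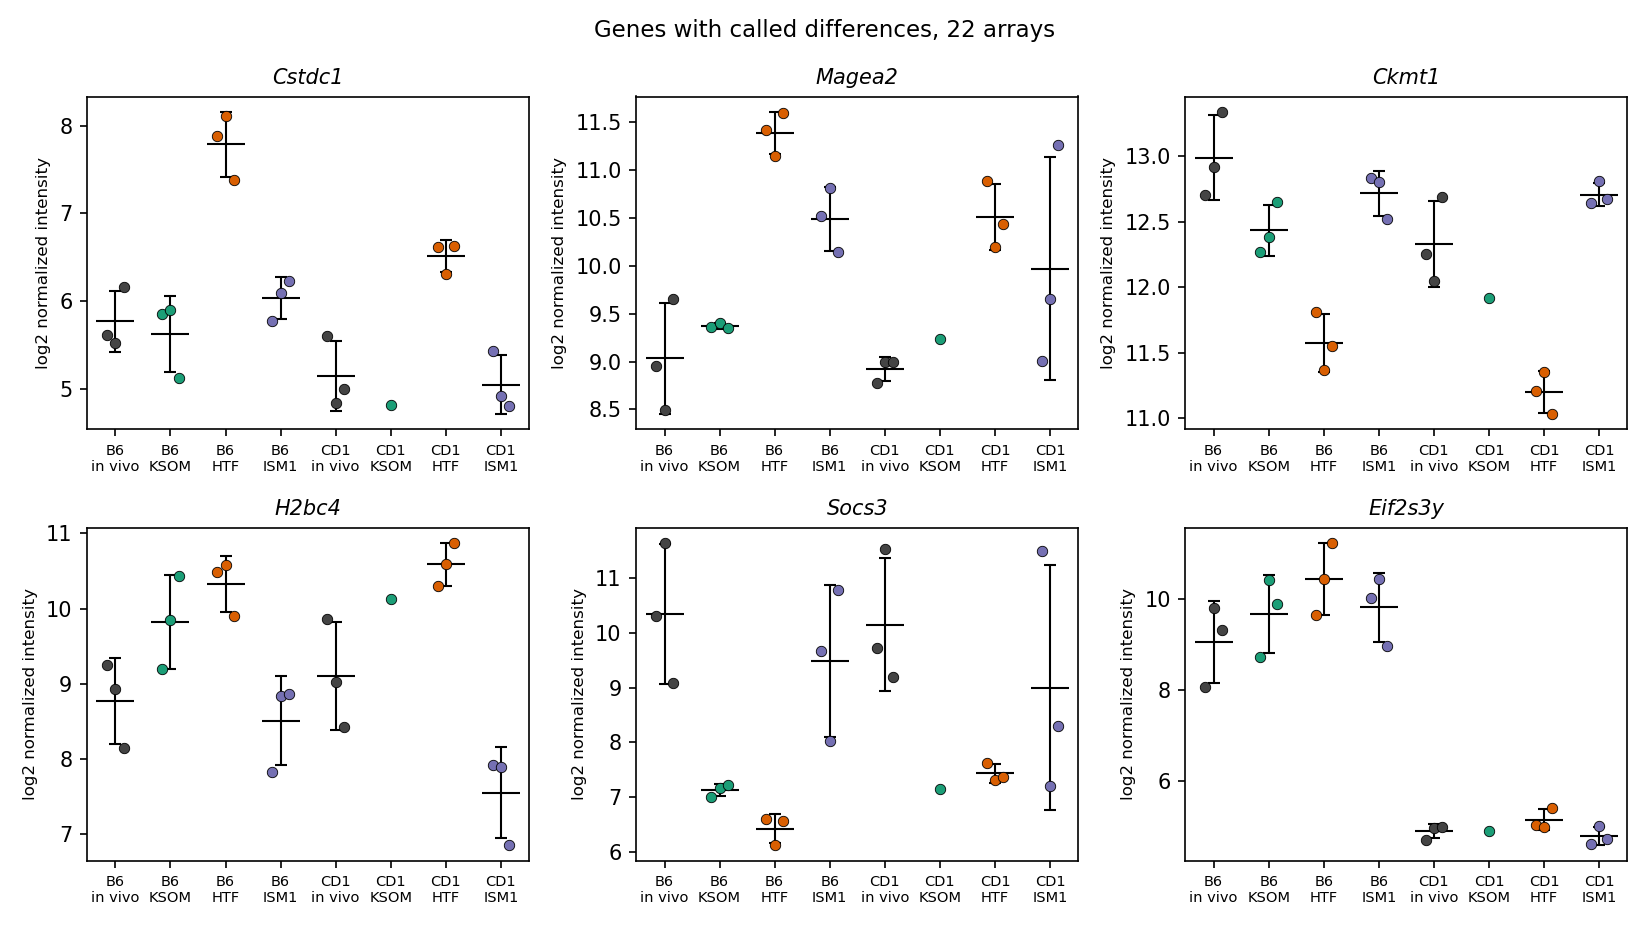
Log2 normalized intensity of Cstdc1, Magea2, Ckmt1, H2bc4, Socs3 and Eif2s3y on each array (points) in the 8 groups, with horizontal marks at the group mean and error bars of 1 SD (n = 3; CD1 KSOM n = 1, no bar). Cstdc1 reached 7.79 in B6 HTF and 6.52 in CD1 HTF, and Eif2s3y lay between 8.06 and 11.3 on the B6 arrays and between 4.61 and 5.40 on the CD1 arrays.

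The gene lists asked which processes differed as a whole. The endoplasmic reticulum stress list, whose 17 measured genes encode chaperones and other factors of protein folding and quality control, was higher in HTF than in vivo in both strains. In B6, 16 of 17 genes were higher, with a median log2 difference of 0.80 (adjusted p = 2.61e-07 by limma's camera). With an estimated correlation the adjusted p was 0.00791. In CD1, 15 of 17 were higher, with a median of 0.82 (adjusted p = 6.39e-06 by camera, and 0.0164 with an estimated correlation). With an estimated correlation the CD1 call was lost when log2 median intensity was a covariate (adjusted p = 0.0902) and without the 3 dimmest arrays (0.123), while the B6 call was made in both settings (0.0189 and 0.0236). The CD1 difference of the list mean did not shrink along with the call: it was 0.79 (SE 0.17), 0.78 (SE 0.20) with the covariate and 0.86 (SE 0.20) without the 3 dimmest arrays. With that correlation the CD1 call was also lost without CD1 HTF replicate 1 (0.0589) or without CD1 in vivo replicate 1, 2 or 3 (0.0534, 0.105 and 0.114), whereas the B6 call was made without each array. The mean log2 level of the list was 9.53 ± 0.11 (SD, n = 3) in B6 HTF and 8.77 ± 0.26 in B6 in vivo, and 9.56 ± 0.24 in CD1 HTF and 8.77 ± 0.24 in CD1 in vivo. The strain difference in this effect was not called (adjusted p = 0.828 by camera, and 0.942 with an estimated correlation). Averaged over the strains, the list mean was 0.78 higher in HTF, and a two-sided exact permutation test within strains gave p = 0.005, the smallest that its 400 relabelings allow, or 0.0383 adjusted over the 23 lists. Among single genes of the list in this average, Hspa5, the chaperone BiP, differed by 1.18 (SE 0.27), Pdia6, a protein disulfide isomerase, by 1.46 (SE 0.43), and Xbp1, a transcription factor of the unfolded protein response, by 0.99 (SE 0.28). Over all genes limma called 1 member, Ero1b. Adjusted over the list alone it called 7: Hspa5, Xbp1, Pdia6, Creld2, Ero1b, Syvn1 and Wfs1. Within a strain, 0 members were called over all genes, while 0 in B6 and 3 in CD1 (Hspa5, Creld2 and Ero1b) were called adjusted over the list alone. Under median scaling and relative to the shift of all genes, the list medians remained positive at 0.76 in B6 and 0.95 in CD1.

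**Figure D2:**
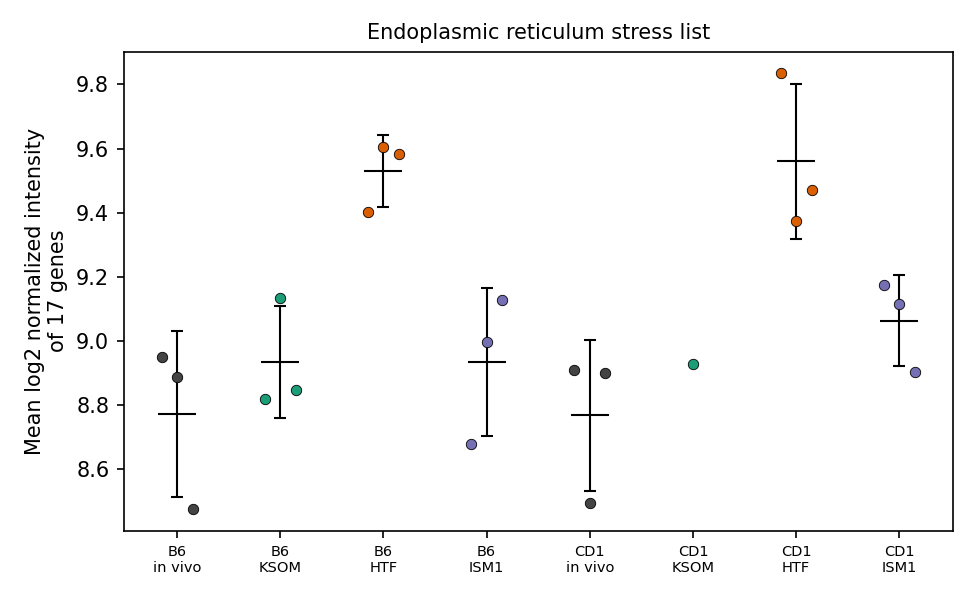
Mean log2 normalized intensity of the 17 genes of the endoplasmic reticulum stress list on each array (points) by group, with group means and error bars of 1 SD (n = 3; CD1 KSOM n = 1). The HTF means were 9.53 in B6 and 9.56 in CD1, against 8.77 in vivo in each strain.

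**Figure D3:**
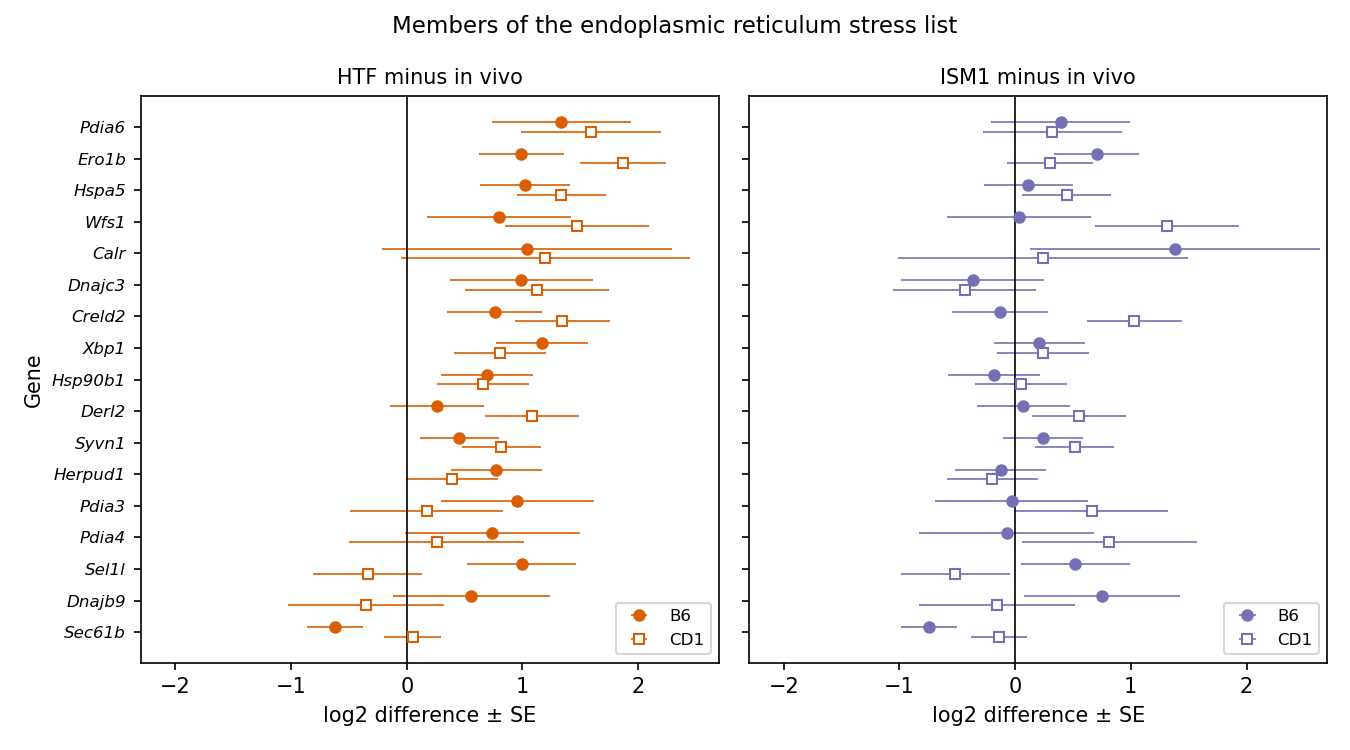
Log2 difference from in vivo (x axis, ± SE) of each gene of the endoplasmic reticulum stress list (y axis) for HTF and for ISM1, with B6 as filled and CD1 as open symbols. For HTF, 16 of 17 genes in B6 and 15 of 17 in CD1 lay above 0.

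The comparison of HTF with in vivo also moved other lists under the preset correlation of camera. Cholesterol synthesis genes were higher in HTF in both strains, with a median log2 difference of 1.18 in B6 (15 of 18 genes, adjusted p = 1.77e-05 by camera) and 1.11 in CD1 (17 of 18, adjusted p = 0.000794). With an estimated correlation these adjusted p were 0.385 and 0.561, and the exact permutation test over both strains gave p = 0.055. On B6 in vivo replicate 3 the mean level of this list, 10.2, lay above all B6 HTF arrays, while the other B6 in vivo arrays had 8.35 and 8.48. The B6 median was 0.76, 0.67 or 1.84 without in vivo replicate 1, 2 or 3. In CD1 the call was lost without in vivo replicate 3 (median 0.67). Oxidative phosphorylation genes were lower, with a median of -0.48 in B6 (65 of 68 genes, adjusted p = 1.22e-19 by camera) and -0.16 in CD1 (46 of 68, adjusted p = 0.0382), and the adjusted p with an estimated correlation was 0.072 and 0.669. The CD1 call was lost without HTF replicate 1 or in vivo replicate 2 or 3 (medians -0.08, -0.02 and -0.10), and the median was -0.34 without in vivo replicate 1. In B6, genes of genome activation at the 2-cell stage had a median of -0.95 (10 of 13 lower, adjusted p = 0.00643 by camera, 0.385 with an estimated correlation), which became -0.64 with undetected groups at their floor. This call was lost without B6 in vivo replicate 1 (median -0.29) or B6 HTF replicate 1 (-0.78), and the median was -1.74 without in vivo replicate 2. Sex-linked genes in B6 had a median of 0.57 (5 of 5 higher, adjusted p = 0.0114 by camera, 0.172 with an estimated correlation), a call lost without B6 HTF replicate 3 (0.36) or in vivo replicate 1 (0.55). This list joins the X-linked Xist with the Y-linked Eif2s3y, Usp9y, Uty and Kdm5d. Its direction, here and in the other contrasts, therefore does not tell which way the sex makeup of the embryos differed. Ribosomal protein genes in B6 had a median of -0.19 (adjusted p = 0.0047 by camera, 0.535 with an estimated correlation), lost as a call without B6 HTF replicate 3 (-0.12) or in vivo replicate 3 (-0.08). It was -0.30 without HTF replicate 1 and -0.33 without in vivo replicate 2. In CD1, primitive endoderm genes had a median of -0.46 (14 of 18 lower, adjusted p = 0.0382 by camera, 0.561 with an estimated correlation) and oocyte transcripts one of -0.51 (16 of 23 lower, adjusted p = 0.00244 by camera, 0.483 with an estimated correlation). The oocyte difference rested on CD1 in vivo replicate 1, with a mean level of 8.32 against 6.52 and 6.59 on the other in vivo arrays, and without it the median was 0.15 without a call. The primitive endoderm call was lost without CD1 HTF replicate 1 or 3 (-0.52 and -0.41) or in vivo replicate 2 or 3 (-0.14 and -0.30), and the median was -0.88 without in vivo replicate 1. No member of these lists was called in these 2 contrasts over all genes. Adjusted over the list alone, the single call among them was P4ha2, a collagen hydroxylase of the primitive endoderm list, in B6 (log2 -0.99, SE 0.28). Averaged over the strains, camera called cholesterol synthesis (median 1.05, adjusted p = 8.28e-07, 0.336 with an estimated correlation), oxidative phosphorylation (median -0.33, 1.5e-11 and 0.213), sex-linked genes (median 0.82, 0.00513 and 0.142), oocyte transcripts (median -0.26, 0.00562 and 0.336), primitive endoderm (median -0.44, 0.00837 and 0.336) and genome activation (median -0.58, 0.0149 and 0.39). Of these calls, that of oocyte transcripts was lost without CD1 in vivo replicate 1 (-0.09), and their median was -0.40 or -0.46 without in vivo replicate 2 of B6 or CD1. Primitive endoderm lost its call without B6 in vivo replicate 2 (-0.28) or CD1 in vivo replicate 2 or 3 (-0.26 and -0.38) and had -0.67 without CD1 in vivo replicate 1. Genome activation lost it without B6 in vivo replicate 1 (-0.51), CD1 HTF replicate 3 (-0.53) or CD1 in vivo replicate 1 (-0.23). In the exact permutation test of HTF against in vivo within strains, the imprinted list (0.29 higher) and the sex-linked list (0.79 higher) also reached p = 0.005, or 0.0383 adjusted over the 23 lists, though camera with an estimated correlation called neither.

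The comparison of ISM1 with in vivo asked the same question of the third medium. Limma called 0 genes in B6 and 0 in CD1, and 111 and 471 genes had an unadjusted p under 0.05. The arrays were fully separated for 8.28% of genes in B6 and 5.2% in CD1, where chance gives 10%. In B6, the count was 1329 with array quality weights and 0 in all other settings. In CD1, it was 2 or 1 without ISM1 replicate 1 or 3 and 2 or 5 without in vivo replicate 1 or 3, and 0 in the other settings. Lxn, a carboxypeptidase inhibitor chosen after its values were seen, had a log2 difference of -1.46 (SE 0.28, adjusted p = 0.412 by limma) in CD1 and -0.97 in B6. H3c4, H3c1 and H4c11, histone genes also chosen after their values were seen, differed by -1.87, -2.52 and -2.25 in CD1 without a call. Averaged over the strains, a contrast chosen after seeing the data, limma called 0 genes, 307 had an unadjusted p under 0.05, and Lxn was lower on all ISM1 arrays than on the in vivo arrays of their strain (log2 -1.21, SE 0.20, adjusted p = 0.0883 by limma). This count was 1 with array quality weights, with no filter and without CD1 in vivo replicate 3. The cholesterol synthesis list was higher in ISM1, with a median of 0.68 in B6 (adjusted p = 0.000352 by camera, 0.757 with an estimated correlation) and 0.89 in CD1 (adjusted p = 0.00136 by camera, 0.453 with an estimated correlation), and the exact permutation test over both strains gave p = 0.14. The groups overlapped through single arrays: the mean level was 8.51 on B6 ISM1 replicate 3 against 10.4 and 10.3 on the others, 10.2 on B6 in vivo replicate 3 against 8.35 and 8.48, and 8.27 on CD1 ISM1 replicate 1 against 10.2 and 9.94. The B6 call was lost without ISM1 replicate 1 or in vivo replicate 1 or 2 (medians 0.44, 0.27 and 0.34), and the median was 0.41, 1.36 and 1.42 without ISM1 replicate 2, ISM1 replicate 3 and in vivo replicate 3. In CD1 it was lost without ISM1 replicate 2 or 3 or in vivo replicate 3 (0.48, 0.47 and 0.56), with 1.68 and 1.39 without ISM1 replicate 1 and in vivo replicate 1. In B6, oxidative phosphorylation had a median of -0.28 (adjusted p = 9.57e-08 by camera, 0.636 with an estimated correlation), ribosomal proteins one of -0.15 (0.00102 and 0.757) and sex-linked genes one of 0.59 (0.0135 and 0.458). The ribosomal call was lost without B6 ISM1 replicate 3 (-0.09) or in vivo replicate 3 (-0.03), with -0.25 without in vivo replicate 2. The sex-linked call was lost without ISM1 replicate 1 or 2 (0.52 and 0.44) or in vivo replicate 1 (0.46). The endoplasmic reticulum stress list was not called in either strain. Averaged over the strains, camera called the p53 target list (median 0.36, adjusted p = 0.00867), the primitive endoderm list (median -0.42, 0.0263), cholesterol synthesis (median 0.82, 4.8e-07) and oxidative phosphorylation (median -0.24, 4.8e-07), each with 0.374 with an estimated correlation, and ribosomal proteins (median -0.14, 0.00801, 0.554 with an estimated correlation). The p53 call was lost without B6 ISM1 replicate 2 (0.27), B6 in vivo replicate 2 (0.27), CD1 ISM1 replicate 2 (0.20) or CD1 in vivo replicate 2 or 3 (0.18 and 0.42). That of primitive endoderm was lost without these arrays (-0.38, -0.27, -0.38, -0.17 and -0.29) or CD1 ISM1 replicate 3 (-0.32). That of ribosomal proteins was lost without B6 ISM1 replicate 3, B6 in vivo replicate 3, CD1 ISM1 replicate 1 or CD1 in vivo replicate 3 (-0.09, -0.06, -0.08 and -0.10). Median scaling shifted the median of all genes by 0.172 in the CD1 comparison.

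KSOM was compared with in vivo growth in B6 alone. Limma called 0 genes, 553 had an unadjusted p under 0.05, and 8.19% of genes had fully separated arrays, where chance gives 10%. The lowest adjusted p was 0.0565, for Phf11a, an interferon-inducible PHD finger gene chosen after its values were seen, with a log2 difference of -3.85 (SE 0.60) and -3.93 on its other probe. The count was 423 with array quality weights, 1 with a detection p under 0.01 and 2 with all probes, the authors' values, median scaling, a trended robust prior or the stage score as a covariate. Without B6 KSOM replicate 2 it was 35. The list of genome activation at the 2-cell stage was lower in KSOM, with a median log2 difference of -1.20 (11 of 13 genes lower, adjusted p = 0.000432 by camera, 0.445 with an estimated correlation). With undetected groups at their floor this median was -0.49. Without B6 in vivo replicate 1 it was -0.35 and the call was lost, and without in vivo replicate 2 it was -1.84. Tcstv1 and Tdpoz1, transcripts of the 2-cell stage, differed by -3.62 (SE 1.44) and -3.04 (SE 1.12), and neither was called over all genes or over the list alone.

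Within B6, the media were compared with each other. Cstdc1 was 4.48-fold lower in KSOM than in HTF (log2 difference -2.16, SE 0.30, adjusted p = 0.0133 by limma), the only gene called of 891 with an unadjusted p under 0.05. Without B6 KSOM replicate 2 the count was 129, and it was 0 without B6 KSOM replicate 3, B6 HTF replicate 1 or B6 HTF replicate 2. It was 221 with array quality weights and 0 with the authors' values, with the replicate block, with only the compared arrays and without the 3 dimmest arrays. Between KSOM and ISM1 limma called 0 genes, 1150 had an unadjusted p under 0.05, and 16% of genes had fully separated arrays. That count was 555 with array quality weights, 5 without background correction, 3 without a filter, 1 with median scaling or the RMA-style background, 296 without B6 KSOM replicate 2 and 4 without B6 ISM1 replicate 3. The lowest adjusted p was 0.0731, shared by Phf11a (log2 -3.26), Lxn (log2 1.71) and Nrl, a transcription factor at least 2.21-fold higher in KSOM, all chosen after their values were seen. Between ISM1 and HTF limma called 0 genes and 172 had an unadjusted p under 0.05. That count was 669 with array quality weights and 1 without background correction or with the RMA-style background. The arrays were fully separated for 15% of genes between KSOM and HTF and 10.2% between ISM1 and HTF. The endoplasmic reticulum stress list was lower in ISM1 than in HTF (median -0.81, 15 of 17 genes, adjusted p = 1.79e-07 by camera, 0.00591 with an estimated correlation). It was also lower in KSOM than in HTF (median -0.54, 14 of 17, adjusted p = 0.000732 by camera, 0.127 with an estimated correlation). Over all genes 0 of its members were called, and adjusted over the list alone Hspa5 and Herpud1 were called between KSOM and HTF. Oxidative phosphorylation genes were higher in KSOM than in HTF (median 0.61, 61 of 68 genes, adjusted p = 3.35e-13 by camera, 0.229 with an estimated correlation), with 10 members called adjusted over the list alone, including Ndufs8, Sdhb and Cox6a1, and 0 over all genes. They were higher in ISM1 than in HTF by a median of 0.24 (adjusted p = 1.69e-06 by camera, 0.725 with an estimated correlation) and in KSOM than in ISM1 by one of 0.36 (0.00113 and 0.754). Without B6 KSOM replicate 3 the median was 0.36 between KSOM and HTF, and 0.15 without a call between KSOM and ISM1. Cholesterol synthesis genes were lower in KSOM than in HTF (median -0.89, adjusted p = 0.000681 by camera, 0.652 with an estimated correlation) and than in ISM1 (median -0.56, adjusted p = 0.0327 by camera, 0.754 with an estimated correlation). Hsd17b7, a sterol reductase, was the single member called adjusted over the list alone in each. The call between KSOM and ISM1 was lost without KSOM replicate 2 (-0.64) or ISM1 replicate 1 or 2 (-0.28 and -0.41), and the median was -1.21 without ISM1 replicate 3.

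ISM1 was compared with HTF in CD1 and over both strains. In CD1, limma called 4 genes, 1 higher and 3 lower in ISM1, and 335 had an unadjusted p under 0.05. H2bc4, a histone H2B gene, was 8.17-fold lower in ISM1 (log2 difference -3.03, SE 0.44, adjusted p = 0.0225 by limma), and Ckmt1 was 2.84-fold higher (log2 1.51, SE 0.24, adjusted p = 0.0366 by limma). Tgfbr2, a receptor of TGF-beta, was at least 3.46-fold lower (adjusted p = 0.0411 by limma). BC048679, chosen after its values were seen, differed by -1.31 (adjusted p = 0.0366 by limma). The same differences in B6 were -1.81 for H2bc4, 1.14 for Ckmt1 and -1.23 for Tgfbr2 without a call, and the strain difference was not called for any of them (each adjusted p = 1 by limma). The CD1 count was 0 without any 1 of the CD1 HTF arrays or CD1 ISM1 replicate 1, 2 without CD1 ISM1 replicate 2 and 1 without CD1 ISM1 replicate 3. Replicate numbers were taken to pair the arrays of this comparison, and with the replicate block the count was 0. It was also 0 when only the 6 arrays were fitted, 1 with median scaling, the authors' values, a detection p under 0.01 or all probes, and 7 with no filter. Averaged over the strains, a contrast chosen after seeing the data, 9 genes were called, 2 higher and 7 lower in ISM1, of 506 with an unadjusted p under 0.05. H2bc4 was 5.36-fold lower (log2 -2.42, SE 0.31), Cstdc1 3.06-fold lower (log2 -1.61, SE 0.21) and Ckmt1 2.50-fold higher (log2 1.32, SE 0.17), each with adjusted p = 0.00221 by limma, and these 3 genes were called in each of 26 settings. Pdlim1 was also higher, and Uchl1 (at least 3.18-fold), Tgfbr2 (at least 2.84-fold) and Cd28 were lower, though the second probe of Cd28 differed by -0.51. Gm773 (log2 -3.37) and BC048679 were chosen after their values were seen. This count was 5 without B6 HTF replicate 1, CD1 HTF replicate 2 or CD1 HTF replicate 3, 4 without B6 ISM1 replicate 1 or 3, 5 with the replicate block or the authors' values, and 315 with array quality weights. In CD1 the endoplasmic reticulum stress list was lower in ISM1 (median -0.53, 14 of 17 genes, adjusted p = 0.00135 by camera, 0.104 with an estimated correlation) and over both strains (median -0.46, 16 of 17, adjusted p = 3.26e-07 by camera, 0.00695 with an estimated correlation). The latter became 0.0529 without the 3 dimmest arrays, where the list mean differed by -0.51 (SE 0.13) in place of -0.55 (SE 0.12). The CD1 call was lost without CD1 HTF replicate 1 (median -0.34), and the median was also -0.34 without CD1 ISM1 replicate 1. Over both strains 0 members were called over all genes and 7 adjusted over the list alone, including Dnajc3, a co-chaperone that differed by -1.46 (SE 0.44). In the exact permutation test its difference was -0.55 with p = 0.005, or 0.115 adjusted over the 23 lists. Over both strains camera also called oxidative phosphorylation (median 0.09, adjusted p = 0.022, 0.787 with an estimated correlation) and oocyte transcripts (median 0.32, adjusted p = 0.028, 0.596 with an estimated correlation). The former was lost without B6 HTF replicate 3, B6 ISM1 replicate 2, CD1 HTF replicate 1 or CD1 ISM1 replicate 2 (0.04, 0.07, 0.04 and 0.06). The latter was lost without B6 HTF replicate 1 or 3 (0.30 and 0.28), B6 ISM1 replicate 1 or 2 (0.18 and 0.24), CD1 HTF replicate 1 or 2 (each 0.32) or CD1 ISM1 replicate 2 (0.25), with 0.56 without B6 ISM1 replicate 3. Median scaling shifted the median of all genes by -0.145 in CD1.

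HTF and ISM1 together were compared with in vivo over both strains. Limma called 2 genes, both higher in culture, of 572 with an unadjusted p under 0.05. Magea2 was 3.05-fold higher (log2 difference 1.61, SE 0.26, adjusted p = 0.0436 by limma), with every cultured array above the in vivo arrays of its strain. Magea5, chosen after its values were seen, differed by 1.40 (SE 0.22, adjusted p = 0.0436 by limma), but by 0.18 on its other probe. Lxn, chosen after its values were seen, was lower on all cultured arrays without a call (2.01-fold, adjusted p = 0.0514 by limma). The count was 0 without any 1 of the HTF arrays of either strain, B6 ISM1 replicate 1 or 2, B6 in vivo replicate 1 or 2, CD1 ISM1 replicate 2 or CD1 in vivo replicate 1 or 2. It was 9 without CD1 ISM1 replicate 1 and 13 without CD1 in vivo replicate 3, 9 with array quality weights and 0 with all probes, the replicate block or only the compared arrays. Averaged over these media, the endoplasmic reticulum stress list was higher than in vivo (median 0.49, 16 of 17 genes, adjusted p = 1.85e-06 by camera, 0.0157 with an estimated correlation), with 0 members called over all genes and 3 adjusted over the list alone. Most of this shift came from HTF. The list mean over both strains was 0.78 above in vivo in HTF and 0.23 in ISM1 (exact permutation p = 0.005 and 0.105). KSOM was not part of this contrast. The call with an estimated correlation was lost with log2 median intensity as a covariate (adjusted p = 0.0503) and without the 3 dimmest arrays (0.0534). The difference of the list mean was 0.50 (SE 0.10), and 0.50 (SE 0.11) and 0.56 (SE 0.12) in these settings, so the SE rose while the difference stayed. It was also lost without B6 in vivo replicate 3 (0.0986) or CD1 in vivo replicate 1, 2 or 3 (0.055, 0.0684 and 0.0598). Camera with the preset correlation further called cholesterol synthesis (median 0.97, adjusted p = 1.62e-08, 0.208 with an estimated correlation), oxidative phosphorylation (median -0.28, 8.61e-12 and 0.203), primitive endoderm (median -0.35, 0.00528 and 0.244) and p53 targets (median 0.32, 0.0125 and 0.395). It also called sex-linked genes (median 0.57, 0.00701 and 0.184), ribosomal proteins (median -0.11, 0.0105 and 0.501), genome activation (median -0.20, 0.0137 and 0.395) and oocyte transcripts (median -0.22, 0.0437 and 0.498). Without 1 array, the calls of cholesterol synthesis, oxidative phosphorylation and sex-linked genes were all made, with a sex-linked median of 0.32 without B6 in vivo replicate 1. Primitive endoderm lost its call without B6 in vivo replicate 2 (-0.26) or CD1 in vivo replicate 2 or 3 (-0.23 and -0.38), with -0.59 without CD1 in vivo replicate 1. The p53 targets lost theirs without B6 in vivo replicate 2 (0.14), CD1 ISM1 replicate 2 (0.17) or CD1 in vivo replicate 2 or 3 (0.10 and 0.28), with 0.21 without CD1 HTF replicate 1. Ribosomal proteins lost theirs without B6 in vivo replicate 3 (-0.05), CD1 ISM1 replicate 1 (-0.07) or CD1 in vivo replicate 3 (-0.08), with -0.17 without B6 in vivo replicate 2. Genome activation lost its call without in vivo replicate 1 of either strain (each -0.17). Its median was -0.61 and -0.63 without B6 in vivo replicate 2 and 3, -0.56 without CD1 in vivo replicate 3, -0.51 without B6 ISM1 replicate 3, -0.41 without B6 HTF replicate 3, -0.39 without CD1 HTF replicate 2, and -0.40, -0.31 and -0.31 without CD1 ISM1 replicate 1, 2 and 3. Oocyte transcripts lost their call without B6 HTF replicate 1 or 3 (-0.16 and -0.14), B6 ISM1 replicate 3 (-0.12), B6 in vivo replicate 1 or 3 (-0.12 and -0.17), CD1 HTF replicate 1 or 2 (each -0.17) or CD1 ISM1 replicate 1 (-0.13). Without CD1 in vivo replicate 1 their median was 0.12, the other way, without a call. The trophectoderm list (median -0.30) and the imprinted list (median 0.16) each had an adjusted p of 0.0543. Median scaling shifted the median of all genes by 0.104.

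The remaining lists were not called by camera in any contrast. Their lowest adjusted p over the contrasts was 0.0855 for reproductive tract epithelium, 0.139 for fluid transport and cell junctions, 0.162 for DNA methylation and chromatin, 0.18 for the cell cycle and DNA replication, 0.202 for cumulus cells, 0.217 for the amino acid starvation response, 0.246 for oxidative stress, 0.283 for glycolysis, 0.329 for epiblast and inner cell mass, 0.393 for heat shock and 0.507 for amino acid transporters. Over the planned contrasts, camera made 38 calls with the preset correlation, 4 with an estimated correlation, all of them of the endoplasmic reticulum stress list, and fry made 6.

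The strains were compared to ask whether the effect of a medium depended on the embryo's background. Limma called 0 genes for the strain difference in the effect of HTF, of ISM1 and of ISM1 against HTF, with 186, 222 and 56 genes at an unadjusted p under 0.05, and these counts were 0 in every setting tried. Across genes, which are not independent replicates, the HTF effects of the strains correlated with r = 0.354 and rho = 0.269, and 58.5% of genes had the same sign. A two-sided exact permutation test over 400 relabelings gave p = 0.2 (smallest possible 0.005). Leaving out 1 array gave r between 0.164 and 0.447, and the latter, without B6 in vivo replicate 3, was the single one with an exact p under 0.05. For ISM1, r was 0.132, rho 0.0899 and p = 0.84 by the same exact test. The strains shared 0 called genes in either medium. Effects within a strain share their in vivo arrays: HTF and ISM1 correlated with r = 0.589 in B6 and 0.624 in CD1, where simulations without effects gave 0.503 in each. KSOM correlated with HTF at 0.306 and with ISM1 at 0.0648 in B6, where simulations gave 0.5 and 0.495. The simulations drew each gene independently and with the same spread in every group, unlike the real arrays. Distances from the simulated values therefore do not show an effect or its absence. Median scaling shifted the medians of all genes for the strain differences by 0.334, 0.197 and -0.154.

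In vivo blastocysts of the strains were compared directly. Limma called 1 gene, Eif2s3y, a Y-linked translation initiation factor gene, which was at least 10.7-fold lower in CD1 (log2 difference -4.19, SE 0.50, adjusted p = 0.0015 by limma). An unadjusted p under 0.05 was reached by 898 genes, and 10.4% had fully separated arrays, where chance gives 10%. The count was 6, 3 or 25 without CD1 in vivo replicate 1, 2 or 3, and 0 with array quality weights, with no background correction, with the replicate block and when only the 6 compared arrays were fitted. Averaged over HTF, ISM1 and in vivo, a contrast chosen after seeing the data, 22 genes were called, 11 higher and 11 lower in CD1, of 948 with an unadjusted p under 0.05. Eif2s3y was at least 20.9-fold lower (log2 -4.85, SE 0.29, adjusted p = 2.96e-08 by limma) and was detected on 12 of 12 B6 arrays and 1 of 10 CD1 arrays. Timmdc1, an assembly factor of respiratory complex I, was 3.35-fold higher (log2 1.74, SE 0.26, adjusted p = 0.00844 by limma). Ggct, a gamma-glutamylcyclotransferase, was also called higher, and its other probes were higher too. Eif2s3y and Timmdc1 were called in each of 32 settings. Rps6kl1 (at least 2.23-fold) and Trappc12 were also higher, and Aqr, Rmdn3, Tomm22 and Ccdc93 lower, with the second probe of Rmdn3 at 0.01. The count was 2 with the replicate block, 3 with no filter, 5 with the authors' values and 11 with only the compared arrays. It was 69 without CD1 in vivo replicate 1 and 137 with array quality weights. It was 3 without B6 HTF replicate 1 or 2, B6 ISM1 replicate 1 or 2, B6 in vivo replicate 1 or CD1 HTF replicate 1 or 3, and 4 without B6 HTF replicate 3. It was 5 without B6 ISM1 replicate 3, 12 without B6 in vivo replicate 2, 7 without B6 in vivo replicate 3, CD1 HTF replicate 2 or CD1 in vivo replicate 2, and 6 without CD1 ISM1 replicate 3. Median scaling shifted the median of all genes by -0.331 between the in vivo groups and by -0.158 in the averaged contrast, where the split became 10 higher and 48 lower. No list was called between the in vivo groups. In the averaged contrast camera called oxidative phosphorylation (median 0.18, adjusted p = 0.00358, 0.868 with an estimated correlation), a call lost without CD1 ISM1 replicate 2 (0.14).

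Genes of lineage, imprinting and stress were read whatever their result. Of the 16 fixed genes, 12 were measured, and limma called 0 of the 120 tests over the 10 contrasts between groups. An unadjusted p under 0.05 was reached in 7, and the lowest adjusted p was 0.296. The trophectoderm factors Cdx2, Gata3 and Eomes and the epiblast factors Nanog and Sox2 were not called. Pou5f1, which maintains the inner cell mass, differed by -2.13 (SE 0.92) between CD1 and B6 in vivo (adjusted p = 0.476 by limma). This difference rests in part on CD1 in vivo replicate 2. The CD1 KSOM array differed from the CD1 in vivo mean by 0.75, and by -0.30 without that replicate. Gata6, a primitive endoderm factor, differed by -0.64 between KSOM and in vivo in B6 (adjusted p = 0.834 by limma), and Mest, an imprinted gene, by 1.07 between KSOM and ISM1 (adjusted p = 0.296 by limma). Asns, an amino acid response gene, differed by -1.02 between HTF and in vivo over the strains (adjusted p = 0.429 by limma). H19, Hspa1b and Trp53 had no probe in the table used, and the probe of Peg3 was detected on 0 arrays.

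The distance between arrays asked how far each medium lay from in vivo growth over all genes. In B6, the mean Euclidean distance to the in vivo mean was 76.3 ± 26.5 (SD, n = 3) for KSOM, 59.0 ± 4.82 for HTF and 60.4 ± 1.11 for ISM1. In vivo arrays of B6 lay 83.0 ± 23.9 from the mean of the other in vivo arrays. In CD1, the distance was 66.9 ± 2.59 for HTF and 78.7 ± 15.7 for ISM1, against 111 ± 16 for in vivo arrays. One-sided exact permutation tests gave p = 0.55, 0.85 and 0.75 in B6 and p = 1 for both media in CD1, where the smallest possible p was 0.05. These values do not part distance from scatter. In CD1 the mean pairwise distance was 128 among in vivo arrays, 99.1 between HTF and in vivo arrays and 62.5 among HTF arrays. In vivo arrays were also set against a mean of fewer arrays, which by itself raises their distance.

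**Figure D4:**
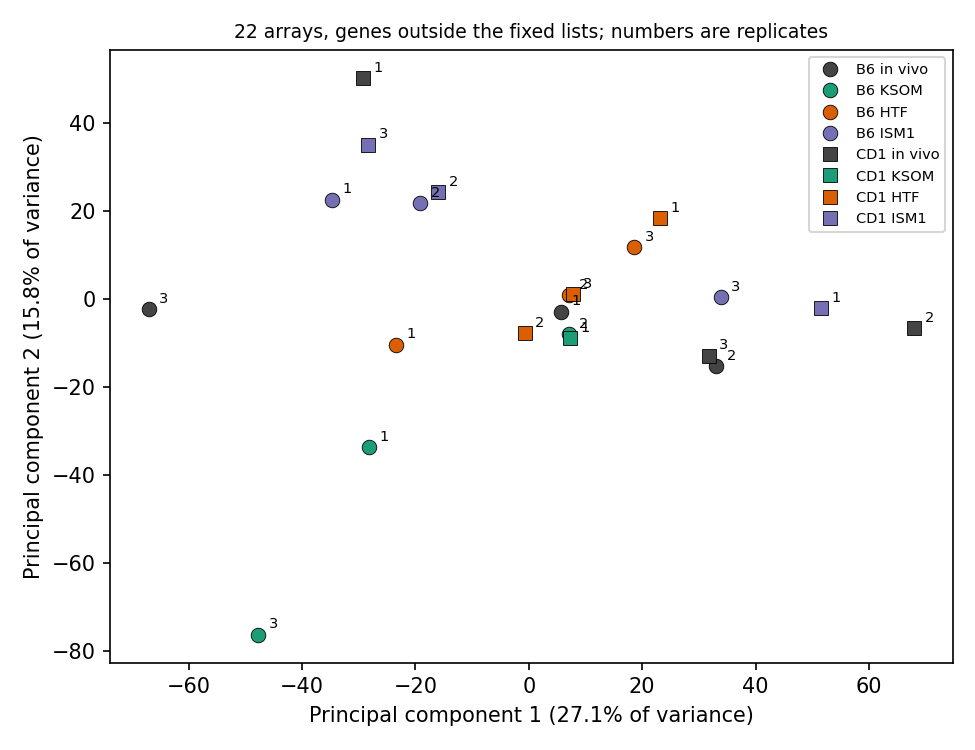
Principal components 1 (x axis, 27.1% of variance) and 2 (y axis, 15.8%) of the 22 arrays over the genes outside the fixed lists, with B6 as circles, CD1 as squares, colour by medium or in vivo growth and numbers for replicates. The groups overlapped, and 15 arrays correlated better with the closest other group of their strain than with their own.

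The CD1 KSOM array had no replicate and was set beside the CD1 in vivo mean without a test. Of 23 lists, 5 had a median outside the central 95% of random lists of matched expression. These were cholesterol synthesis (log2 0.55, percentile 99.9), oxidative phosphorylation (0.26, percentile 99.6), ribosomal proteins (0.22, percentile 99.4), genome activation (-0.50, percentile 1.14) and oocyte transcripts (-0.50, percentile 0.01). None of the 5 stayed outside without each in vivo array. Without CD1 in vivo replicate 1, the median was 0.06 for oocyte transcripts (percentile 73.2), -0.20 for genome activation (percentile 20.3), 0.02 for oxidative phosphorylation (percentile 24.1) and 0.17 for ribosomal proteins (percentile 94.1). For cholesterol synthesis it was 1.17 without that array and 0.27 (percentile 86.4) without in vivo replicate 3. Oxidative phosphorylation had 0.42 without in vivo replicate 2, and genome activation -0.80 without in vivo replicate 3. Other lists came to lie outside. Without in vivo replicate 1 these were trophectoderm (-0.49), primitive endoderm (-0.82), fluid transport and cell junctions (-0.29), amino acid transporters (-0.46) and p53 targets (0.77). Without in vivo replicate 2 they were the amino acid starvation response (-0.24), heat shock (-0.24) and blood and immune cells (0.58). The endoplasmic reticulum stress list had a median of 0.24 at percentile 81.3, and of 0.11 without in vivo replicate 1. Among fixed genes, Gata3 differed by -2.59, Asns by -1.31, Mest by 0.98 and Pou5f1 by 0.75. Pou5f1 differed by 1.57 without in vivo replicate 1 and by -0.30, the other way, without in vivo replicate 2, and Mest by 1.53 without in vivo replicate 3.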

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

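The tests of the exchange of array labels, of the stage score, of Eif2s3y, of the endoplasmic reticulum list with covariates, of the lists without each array, and the splits for KSOM, B6 ISM1 and CD1 ISM1 against in vivo and for the strains in vivo were chosen only after the results were seen.

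In 4 cases a gene list was marked because its effect differed between the strains in a test of that difference. Oxidative phosphorylation was lowered less by HTF in CD1 than in B6 (57 of 68 genes, median difference 0.36, adjusted p = 1.52e-05 by camera, 0.719 with an estimated correlation). In ISM1 against HTF the same list differed the other way (median -0.27, adjusted p = 0.000575 by camera, 0.718 with an estimated correlation). The blood and immune list differed between strains for HTF (7 of 7 genes, median 0.57, adjusted p = 0.0324 by camera, 0.719 with an estimated correlation) and for ISM1 (7 of 7, median 0.94, adjusted p = 0.0101 by camera, 0.488 with an estimated correlation). None of the 4 was called with an estimated correlation or by fry (adjusted p = 0.651 to 0.937), and no single gene of these lists had a called difference between the strains. The oxidative phosphorylation calls were lost without CD1 in vivo replicate 1 for HTF (median 0.19), and without B6 HTF replicate 3, CD1 HTF replicate 3 or CD1 ISM1 replicate 3 for ISM1 against HTF (-0.21, -0.20 and -0.19). For the blood list in HTF the call was lost without B6 HTF replicate 1 (0.53), B6 in vivo replicate 2 or 3 (0.63 and 0.45), CD1 HTF replicate 1 or 3 (0.55 and 0.51) or CD1 in vivo replicate 1 or 3 (0.46 and 0.58), with 0.87 without B6 in vivo replicate 1. In ISM1 it was lost without B6 ISM1 replicate 3 (0.51), B6 in vivo replicate 3 (0.40), CD1 ISM1 replicate 2 (0.48) or CD1 in vivo replicate 1 or 3 (0.69 and 0.57). The HTF and ISM1 differences of the blood list share the same in vivo arrays and are not independent. Of this list, Hba-a1, an alpha globin, was detected on 2 of 3 B6 in vivo arrays and on no cultured B6 array (log2 -1.41 in HTF and -1.29 in ISM1, bounds -0.75 and -0.67). In CD1 it was undetected in vivo and in HTF and detected on 1 ISM1 array.

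Other splits of the same arrays were fitted to ask whether arrays grouped by chance give as many genes. For comparisons of 3 with 3 arrays there are 10 splits, too few for a share under 0.05. For B6 HTF, CD1 HTF and B6 KSOM against HTF, 1 of 10 splits gave as many genes as the real 1, and the highest other split gave 0. For CD1 ISM1 against HTF, 1 of 10 gave as many as the real 4, and the highest other gave 1. The 3 other splits that part each pair of replicate numbers there gave 0. For B6 ISM1 against HTF and B6 KSOM against ISM1 the real count and the highest other were both 0, so 10 of 10 splits gave as many. For the strains in vivo, 5 of 10 splits gave as many as the real 1, and the highest other gave 48. For KSOM, B6 ISM1 and CD1 ISM1 against in vivo the real count was 0, so 10 of 10 splits gave as many, and the highest others gave 167, 7 and 722. Counts of 48, 167 and 722 point to a structure of the arrays that the groups do not describe.

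For contrasts over both strains, 100 splits were drawn. They included the real one and took no account of replicate numbers. For the HTF effect averaged over the strains only the real split gave as many genes (1 of 100, real 19, highest other 8). The same held for CD1 against B6 averaged over HTF, ISM1 and in vivo (1 of 100, real 22, highest other 5). For ISM1 against HTF averaged over the strains another split tied with the real one (2 of 100, real 9, highest other 9). These shares argue against chance assignment as the source of the counts. They do not exclude it, since these contrasts were chosen after seeing the data. For HTF and ISM1 jointly against in vivo the share was also low (3 of 100, real 2), but the highest other split gave 512. For the ISM1 effect averaged over the strains all 100 splits gave as many as the real 0, and the highest other gave 2225. For the strain differences in HTF, ISM1 and ISM1 against HTF all 100 splits gave as many as the real 0, and the highest others gave 9, 1240 and 1. Splits that call 512, 1240 or 2225 genes again point to a structure of the arrays, since they call many times the real count.

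One such split was examined. When CD1 ISM1 replicate 1 and CD1 in vivo replicate 1 change places, limma called 722 genes, 285 higher and 437 lower, where the real grouping called 0. The brightness of the arrays was argued against as the whole source, since 318 genes were still called with log2 median intensity as a covariate. The stage or lineage makeup of the embryos may contribute: within groups, the main axis of the genes outside the lists correlated with the stage score over 21 arrays (r = 0.759, permutation p = 0.00322, rho = 0.73, permutation p = 0.00474, adjusted p = 0.0161 over 25 relations, r = 0.756 without the 2 farthest arrays), as it did with the trophectoderm (0.924), amino acid transporter (0.887), cholesterol synthesis (-0.825), p53 target (-0.773) and reproductive tract (0.735) lists, so that these relations do not single out stage. An exchange of the labels of these arrays stays open and cannot be told apart from it: the oviduct gene Ovgp1 had a log2 level of 8.079 on CD1 in vivo replicate 1 and was undetected on CD1 ISM1 replicate 1, as was Tppp3, while Muc1, Wfdc2 and Foxj1 were detected on both.

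The endoplasmic reticulum stress list was higher in HTF than in vivo in both strains. Chance assignment of arrays was argued against by the exact permutation test (p = 0.005, the smallest possible). With an estimated correlation the adjusted p averaged over the strains was 0.00681 with the stage score as a covariate and 0.00576 with log2 median intensity, and 0.0189 in B6 with the latter, which argues against either as the whole source of these differences. In CD1, whose in vivo arrays were the dimmest group, that adjusted p was 0.0902 with median intensity, so this test did not decide on brightness. With the preset correlation and that covariate camera gave an adjusted p of 0.000166. The CD1 list mean differed by 0.78 (SE 0.20) with the covariate, in place of 0.79 (SE 0.17), and by 0.86 (SE 0.20) without the 3 dimmest arrays. The difference did not shrink, but these settings cannot decide on brightness in CD1. Every CD1 in vivo array was dimmer than every CD1 HTF array (median intensity 90.6 to 111.5 against 113.1 to 138.1), also without the 3 dimmest arrays. Why the call ended was not tested. A response of the embryos to HTF is a hypothesis found and tested on the same data, and a slide or batch difference was not tested, since the slides are not given in the sources used here.

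Eif2s3y was detected on 12 of 12 B6 arrays and 1 of 10 CD1 arrays. Few male embryos in the CD1 samples stays open: Usp9y was higher in CD1 than in B6 (1.47, SE 0.66) and Uty alike (0.02, SE 0.18), each detected on 8 of 10 CD1 arrays, while Kdm5d was lower (-0.46, SE 0.18) and detected on 3 of 10 CD1 and 5 of 12 B6 arrays, each without a call. These genes do not settle it, since 0 of the 3 lay over 2 above the detection floor in B6 on the log2 scale. A strain variant under the probe stays open and could not be tested, since the array has 1 probe of this gene. A strain difference in the transcript itself also stays open and was not tested.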

How the results depend on the processing

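The stage score, the 3 dimmest arrays, the gene lists and the CD1 KSOM comparison without each array and the 4 contrasts averaged over strains or conditions were chosen after seeing the data. Of 474 recomputed values, 316 were scored as the same as in the main fit. Most of the 474 were counts of called genes, scored by how close each stayed to the main count. This score does not show that single genes kept their direction or their call. The 316 include 26 settings for each strain difference in a medium effect, where the count was 0 throughout. The genes called in the contrasts fixed before the data were examined reversed their sign in no setting, kept their call in 114 cases and lost it in 110. In the averaged contrasts, Rmdn3 had the other sign between CD1 and B6 with all probes (log2 0.01), but this value is that of its second probe. With all probes, a gene was read from its first listed kept probe, which need not be the tested one. Such differences are between probes and do not come from the processing. The strain differences stayed at 0 genes in all settings. Mean distances to in vivo were 59 to 78.7, 59.4 to 79.2 with median scaling and 73.9 to 101 with the authors' table. The 3 dimmest arrays were CD1 in vivo replicate 1, CD1 ISM1 replicate 3 and B6 KSOM replicate 3. On simulated data with this number of arrays and this variance, 10 of 100 genes changed by 1 on the log2 scale in B6 HTF against in vivo were called, and 61 of 100 changed by 2. Array signal as a limit was not tested. The cause of the changes below was not tested.

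With array weights, the counts were 423 (B6 KSOM minus in vivo), 1159 (B6 HTF minus in vivo), 1329 (B6 ISM1 minus in vivo), 0 (CD1 HTF minus in vivo), 221 (B6 KSOM minus HTF), 669 (B6 ISM1 minus HTF), 555 (B6 KSOM minus ISM1), 0 (CD1 in vivo minus B6 in vivo), 9 (cultured minus in vivo), 165 (HTF minus in vivo, mean of strains), 1 (ISM1 minus in vivo, mean of strains), 315 (ISM1 minus HTF, mean of strains) and 137 (CD1 minus B6, mean).

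With the RMA-style background they were 4 (B6 HTF minus in vivo), 0 (CD1 HTF minus in vivo), 1 (B6 ISM1 minus HTF) and 1 (B6 KSOM minus ISM1). With no background correction they were 4 (B6 HTF minus in vivo), 2 (CD1 HTF minus in vivo), 1 (B6 ISM1 minus HTF), 5 (B6 KSOM minus ISM1) and 0 (CD1 in vivo minus B6 in vivo). With all probes they were 2 (B6 KSOM minus in vivo), 0 (CD1 HTF minus in vivo), 1 (CD1 ISM1 minus HTF) and 0 (cultured minus in vivo). With no filter they were 3 (B6 HTF minus in vivo), 4 (CD1 HTF minus in vivo), 3 (B6 KSOM minus ISM1), 7 (CD1 ISM1 minus HTF), 1 (ISM1 minus in vivo, mean of strains) and 3 (CD1 minus B6, mean). With a detection p under 0.01 they were 1 (B6 KSOM minus in vivo) and 1 (CD1 ISM1 minus HTF).

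With the authors' table they were 2 (B6 KSOM minus in vivo), 0 (B6 HTF minus in vivo), 0 (B6 KSOM minus HTF), 1 (CD1 ISM1 minus HTF), 5 (ISM1 minus HTF, mean of strains) and 5 (CD1 minus B6, mean). With median scaling they were 2 (B6 KSOM minus in vivo), 2 (B6 HTF minus in vivo), 0 (CD1 HTF minus in vivo), 1 (B6 KSOM minus ISM1), 1 (CD1 ISM1 minus HTF) and 58 (CD1 minus B6, mean). With that scaling camera made 59 list calls over the planned contrasts in place of 38. With a trended robust prior they were 2 (B6 KSOM minus in vivo), 2 (B6 HTF minus in vivo) and 0 (CD1 HTF minus in vivo). Over the planned contrasts, camera with an estimated correlation made 4 list calls, all of the endoplasmic reticulum stress list, and fry made 6.

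Fitting only the compared arrays gave 0 (B6 HTF minus in vivo), 0 (CD1 HTF minus in vivo), 0 (B6 KSOM minus HTF), 0 (CD1 ISM1 minus HTF), 0 (CD1 in vivo minus B6 in vivo), 0 (cultured minus in vivo), 10 (HTF minus in vivo, mean of strains) and 11 (CD1 minus B6, mean), with fewer residual degrees of freedom.

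The replicate block gave 0 (B6 HTF minus in vivo), 0 (B6 KSOM minus HTF), 0 (CD1 ISM1 minus HTF), 0 (CD1 in vivo minus B6 in vivo), 0 (cultured minus in vivo), 7 (HTF minus in vivo, mean of strains), 5 (ISM1 minus HTF, mean of strains) and 2 (CD1 minus B6, mean). Replicate numbers were taken to pair the arrays of CD1 HTF and CD1 ISM1, and the block changed no list call there. In the other comparisons not every pair with the same number had r over 0.1, and over all of them 11 of 27 did, with a range of -0.718 to 0.453. The slide block was not run.

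With the stage score as a covariate they were 2 (B6 KSOM minus in vivo), 2 (B6 HTF minus in vivo), 4 (CD1 HTF minus in vivo), 6 (cultured minus in vivo), 56 (HTF minus in vivo, mean of strains) and 67 (CD1 minus B6, mean). Without the 3 dimmest arrays they were 3 (B6 HTF minus in vivo), 10 (CD1 HTF minus in vivo), 0 (B6 KSOM minus HTF), 14 (CD1 in vivo minus B6 in vivo), 7 (cultured minus in vivo), 38 (HTF minus in vivo, mean of strains) and 102 (CD1 minus B6, mean).

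Leaving out 1 array gave ranges of 0 to 35 (B6 KSOM minus in vivo), 0 to 1 (B6 HTF minus in vivo), 0 to 29 (CD1 HTF minus in vivo), 0 to 5 (CD1 ISM1 minus in vivo), 0 to 129 (B6 KSOM minus HTF), 0 to 296 (B6 KSOM minus ISM1), 0 to 2 (CD1 ISM1 minus HTF), 1 to 25 (CD1 in vivo minus B6 in vivo), 0 to 13 (cultured minus in vivo), 5 to 56 (HTF minus in vivo, mean of strains), 0 to 1 (ISM1 minus in vivo, mean of strains), 4 to 10 (ISM1 minus HTF, mean of strains) and 3 to 69 (CD1 minus B6, mean). The correlation of the HTF effects between strains ranged from 0.164 to 0.447.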
